A study of Mus musculus with 16 samples.

How the data were processed

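DNase-seq of mouse liver was analysed from the peak lists the authors deposited, 16 lists for 16 pools of livers. The pools form 8 groups of 2, by sex (male or female), time after injection (3 h or 27 h) and treatment (TCPOBOP or vehicle). Per the labels, each pool held DNA from 3 to 5 mice of the CD-1 strain, received at 7 weeks of age and injected intraperitoneally with 3 mg/kg TCPOBOP or with vehicle, which was 1% DMSO in corn oil. The labels number the pools of a group 1 and 2 and do not say that equal numbers share mice, a day or a batch. Each combination of sex and time carries its own experiment code, with TCPOBOP and vehicle pools under the same code. TCPOBOP was therefore compared with vehicle within an experiment. A difference between sexes or times is also a difference between experiments and cannot be told apart from one.

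Per the labels' protocols, nuclei were digested with DNase I, short fragments were collected from a sucrose gradient, and beads selected fragments of 125 to 400 bp. Reads were 50 bp long, per the file headers. The 27 h libraries were sequenced from both ends, and only the first read was used, per the labels' protocols. Reads were aligned to the mouse genome build mm9 with Bowtie, per the submitters' processing notes, which give no version. Peaks were called in each pool on its own with MACS 2.1.0.20150731, per the file headers, with no control library, with all duplicate reads kept, with each read end shifted by 100 bp and extended to 200 bp, and at a q-value of 0.05. The headers give the total tags of each library, 15679689 to 43618254. Peaks are numbered in each list up to 29697 to 46803, and 458 to 552 of those numbers were absent from each list, so that some peaks had been removed after calling; the filter is not given in the sources used here.

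The deposited pileup is a signal, the number of extended tags over a peak's summit, and the authors did not scale it to depth, per the file headers. The deposited fold enrichment is the ratio of that pileup to the local background of the same library. The lists also give −log10 of the p-value and −log10 of the q-value, per the file headers. Fold and −log10 q are the authors' own values for each peak, and ranks and filters were made from them within 1 list. Folds averaged or set side by side over lists, and regions chosen by their ranks in several lists, are descriptions only. Each fold is relative to the background of its own library. The heading of 1 list of the female 27 h TCPOBOP pair carries the code of the female 3 h experiment, while its command line and its peak names carry the code of its own experiment; it was used as the latter.

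Before the data were examined, the comparisons, the definitions of gained, lost and strong peaks, the odds ratios of concordance, the rule for naming regions and most alternatives were fixed. That plan assumed 1 list per group. The deposit held 1 list per pool, so a gained peak was defined as a peak of TCPOBOP pool 1 that overlapped a peak of TCPOBOP pool 2 by at least 1 bp and no peak of either vehicle pool, and a lost peak as the reverse. A strong gained or lost peak also had to be among the 20000 peaks ranked highest by −log10 q in both pools of its group and to overlap no peak of the whole lists of the other group. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. With 2 pools against 2 no rearrangement of the pools can give a small p-value, so no p-value was given for these counts. Instead the same count was made in the 2 splits of each comparison that set a TCPOBOP and a vehicle pool against the remaining pair, each counted in both directions, as a measure of variation between pools. Overlaps were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and 8 counts were recomputed with bedtools 2.31.1 and were equal.

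For comparisons across lists, overlapping peaks of all 16 lists were merged into 61240 regions of median width 593 bp, of which 18443 held a peak in all 16 lists and 11017 in 1 list. Concordance between sexes or times was measured as the odds ratio, with an exact 95% interval from scipy 1.17.1, among regions that were gained or lost in both comparisons. The comparisons set against each other do not share vehicle pools. Regions are not replicates, so no p-value was given. Beside most overlaps stands the number of regions that independent lists would share. For gained and lost regions it was first taken over all 61240 regions, which include regions that cannot change, and gave 50.4 and 53.9 for gain in both sexes at 3 h and 27 h. After these values were seen it was replaced by the number among regions with a peak in some but not all lists of both comparisons, which is higher for the gained regions. Such regions still differ in strength, so both numbers are references and not tests.

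A test of the summit pileup was added after the lists were seen, since it uses the spread between pools. For each region the highest pileup of its peaks in a pool was scaled to 1000000 tags of its library, put on the log2 scale and centred on the median of the 18443 regions called in all 16 pools. Pileup is comparable between pools only under this scaling, and the position of the summit can differ between lists. A comparison tested the regions called in all 4 of its pools, so that gained and lost regions are outside it. limma 3.58.1 in R 4.3.3 was fitted to all 16 libraries with 8 group means and a prior variance that follows mean signal. Residual degrees of freedom were 8 for regions called in all 16 pools and fewer for the others. With those of the prior, the median total per comparison was 24.9 to 29.7, so most came from the prior. Benjamini-Hochberg adjustment was made within each comparison at a threshold of 0.05. The groups share 1 estimate of spread per region, so calls in different comparisons are not independent. A group adds to that estimate only where both of its pools were called. The tests are two-sided, and the p-values measure the spread between pools of mice. The test of a difference between sexes or times was the contrast of both effects in the same fit.

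The peaks and regions named were, per comparison, the 10 strong gained and the 10 strong lost peaks of highest −log10 q (the lower of both pools), the 10 regions gained or lost in both sexes or in all 4 comparisons whose lowest rank was best, and for sex the 10 regions present in every vehicle list of 1 sex and in none of the other, chosen likewise; the text prints part of these. Regions named from the pileup test were taken among the 5 of lowest p per direction and comparison, and they, the regions whose effect differed and the groups of neighbouring regions were chosen after their values were seen. A gene table on another genome build, GRCm38.p6, was not used to place regions, since coordinates of different builds were not mixed. Regions are therefore named by their mm9 coordinates, and the planned assignment of regions to genes, the gene lists and the motif search are not analysed here.

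The overlap step was tested on simulated lists of 20000 regions and found 300 of 300 planted gained and 200 of 200 planted lost peaks. The pileup test was tested on the real regions with changes planted in simulated pools. Of 100 regions changed by a log2 of 1, it recovered 61 in males at 3 h (22908 regions), 60 in females at 3 h (22825 regions), 41 in males at 27 h (31915 regions) and 53 in females at 27 h (25502 regions). Of 100 regions changed by a log2 of 2 it recovered 96, 96, 97 and 97 in the same order. False calls numbered 6, 13, 3 and 9. The simulated pools had independent noise with the same spread per region in all groups. The simulation therefore cannot test that assumption or differences in enrichment between libraries.

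The alternatives varied the overlap that counts as shared, the ranking and its depth, a −log10 q of at least 10, lists reduced to the length of the shortest (29216 peaks), autosomes only, the merging of regions, the scaling and filters of pileup, the replicate number as a block, and each pool left out in turn. Chromosomes X, Y and the mitochondrial genome were kept. The limit for reading the test of sex-biased regions was set after its values were seen, as stated beside that test. Figures were drawn with matplotlib 3.10.9.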

Results

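DNase-seq, in which DNase I releases short fragments from accessible chromatin for sequencing, was carried out on livers of male and female mice 3 h or 27 h after 1 injection of TCPOBOP or vehicle. TCPOBOP is a synthetic agonist ligand of the constitutive androstane receptor (CAR), a nuclear receptor that controls drug-metabolising genes in hepatocytes. Each of the 8 groups had 2 pools of mice. The libraries held 15679689 to 43618254 tags, and 29216 to 46281 peaks were called per pool, covering 13.6 to 27.7 Mb of the mm9 genome. The 27 h libraries of males held 28633652 and 36187819 tags after TCPOBOP and 35822318 and 43618254 after vehicle. Pools of the same group shared 75.5 to 94.0% of their peaks, and 95.3 to 99.9% of their 20000 highest-ranked peaks. TCPOBOP and vehicle pools of an experiment shared nearly as many, 70.0 to 94.8% and 95.3 to 99.9%. Log2 pileup across the regions called in both pools of a pair correlated at r = 0.918 to 0.964 between pools of the same group. Between TCPOBOP and vehicle pools of an experiment it correlated at 0.905 to 0.946. These correlations are across regions, which are not independent replicates.

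The male 3 h pools were compared to ask which sites had changed soon after CAR activation in males. Signal was higher after TCPOBOP at 147 of the 22908 regions called in all 4 pools and lower at 26. The median change of the higher regions was log2 0.97 (1.96-fold). The largest was 4.76-fold, at chromosome 7, 26672712 to 26673610, where mean pileup, scaled to 1000000 tags, was 7.30 after TCPOBOP and 1.53 after vehicle (log2 2.25 ± 0.18, SE, n = 2 pools per group, limma adjusted p = 4.23e-08). A neighbouring region on chromosome 7, 26679889 to 26680779, rose by log2 2.12 ± 0.19 (adjusted p = 6.43e-07), chromosome 18, 68650572 to 68651869 by 1.83 ± 0.21 (adjusted p = 3.63e-05), and chromosome 6, 67099388 to 67100258 by 1.25 ± 0.16 (adjusted p = 8.13e-05). Among the lower regions, chromosome 16, 98072557 to 98073794 changed by log2 −1.22 ± 0.21 (adjusted p = 0.00338). The 5 lower regions with the lowest p each missed the threshold when at least 1 pool was left out.

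Peaks absent from vehicle appeared as well. Of the 30145 peaks shared by both male 3 h TCPOBOP pools, 2280 (7.56%, 95% CI 7.27 to 7.87) overlapped no vehicle peak, while 235 of 25374 vehicle peaks (0.926%, CI 0.812 to 1.05) were lost. Splits that mixed TCPOBOP and vehicle pools gave 258 to 1432 such peaks. With all lists at equal length the counts were 924 gained and 774 lost, against 622 to 693 in the mixed splits. Among the 20000 highest-ranked peaks, 67 were gained and 8 lost, against 5 to 23 in the mixed splits. The strong gained peak of highest −log10 q was on chromosome 10, 80420561 to 80421067, with a fold enrichment of 7.14 ± 0.0686 (SD, n = 2 pools). It was followed by chromosome 7, 26682309 to 26682810 at 7.43 ± 0.519, chromosome 19, 39358830 to 39359323 at 5.37 ± 0.614, and chromosome 4, 117005038 to 117005589 at 11.3 ± 0.626. The strong lost peak of highest −log10 q was on chromosome 6, 86476145 to 86477504, with a fold of 7.22 ± 0.325 in vehicle. Without TCPOBOP pool 1, TCPOBOP pool 2 or vehicle pool 2 the regions called higher numbered 14, 51 and 80. With the spread estimated from these 4 libraries alone 14 regions were higher and 0 lower, and without a mean trend in the prior 50 and 6. The regions called lower numbered 2, 14, 13 and 6 without TCPOBOP pool 1, TCPOBOP pool 2, vehicle pool 1 and vehicle pool 2, and leaving out any 1 pool, which counts the peaks of a single list, raised the gained peaks to 3927 to 7828 and the lost to 420 to 1519.

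In females at 3 h, the same question was asked of the other sex. Signal was higher after TCPOBOP at 238 of 22825 regions and lower at 18, with a median of log2 1.07 (2.097-fold) among the higher regions. The largest change was again at chromosome 7, 26672712 to 26673610, an 8.45-fold rise from 0.884 to 7.47 in scaled pileup (log2 3.08 ± 0.18, SE, n = 2 pools per group, limma adjusted p = 1.17e-11). Its neighbour at 26679889 to 26680779 rose by log2 2.38 ± 0.20 (adjusted p = 1.79e-08) and the region at 26674300 to 26675132 by 1.95 ± 0.20 (adjusted p = 1.47e-06). Chromosome 18, 68650572 to 68651869 rose by 2.28 ± 0.21 (adjusted p = 2.00e-07), and chromosome 10, 80421722 to 80422333 by 1.99 ± 0.16 (adjusted p = 1.79e-08). The lower regions included chromosome 19, 36738229 to 36739171, which changed by log2 −0.87 ± 0.17 (adjusted p = 0.00702); the 5 of lowest p each missed the threshold when at least 1 pool was left out.

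The female 3 h TCPOBOP pools shared 28301 peaks, of which 1752 were gained (6.19%, CI 5.91 to 6.48), and 427 of 25919 vehicle peaks were lost (1.65%, CI 1.496 to 1.81). Mixed splits gave 578 to 815. At equal list length 1044 were gained and 771 lost, against 603 to 659. Strong gained peaks numbered 121 and strong lost peaks 7, against 4 to 16 in mixed splits. The strong gained peaks of highest −log10 q were at chromosome 10, 80420568 to 80421070 (fold 8.16 ± 1.59, SD, n = 2 pools), chromosome 19, 39182842 to 39183430 (13.5 ± 0.962), chromosome 4, 19238278 to 19238896 (12.3 ± 1.27) and chromosome 4, 25298977 to 25299482 (14.3 ± 1.38). The lost peak of highest −log10 q was at chromosome 9, 106147602 to 106148003 (5.98 ± 0.132 in vehicle). Without TCPOBOP pool 1, TCPOBOP pool 2, vehicle pool 1 or vehicle pool 2 the regions called higher numbered 155, 153, 91 and 98 and those called lower 31, 67, 1 and 4; from these 4 libraries alone they numbered 149 and 10, and without a mean trend in the prior 146 and 10. Leaving out any 1 pool raised the gained peaks to 2988 to 4315 and the lost to 1239 to 1787.

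The male 27 h pools were compared to see the state of the liver a day later. Signal was higher after TCPOBOP at 557 of 31915 regions, with a median of log2 1.10 (2.14-fold), and lower at 140, with a median of −1.01. The largest change, 9.89-fold, was at chromosome 7, 26681892 to 26682863, where scaled pileup was 7.67 after TCPOBOP and 0.775 after vehicle (log2 3.31 ± 0.23, SE, n = 2 pools per group, limma adjusted p = 4.05e-10). Chromosome 5, 129084925 to 129086402 rose by log2 3.19 ± 0.22 (adjusted p = 3.72e-10), chromosome 4, 117004869 to 117005675 by 2.93 ± 0.22 (adjusted p = 1.18e-09), and chromosome 18, 68650572 to 68651869 by 2.83 ± 0.21 (adjusted p = 4.05e-10). The region at chromosome 10, 80420505 to 80421154, gained at 3 h in both sexes, had peaks in all 4 male 27 h pools and was log2 2.50 ± 0.19 higher after TCPOBOP (adjusted p = 1.18e-09). Chromosome 16, 31651669 to 31652628 changed by log2 −1.35 ± 0.18 (adjusted p = 1.69e-05), and chromosome 5, 140580640 to 140581426 by −1.22 ± 0.19 (adjusted p = 0.000173).

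At 27 h in males, gained peaks did not outnumber lost ones in the whole lists. Over 12 alternative settings, left-out pools included, the ratio of gained to lost peaks ran from 0.491 to 2.77. Of 36872 peaks shared by the TCPOBOP pools 1328 were gained (3.60%, CI 3.41 to 3.797), and 1359 of 38411 vehicle peaks were lost (3.54%, CI 3.36 to 3.73), within the 300 to 1755 of the mixed splits. At equal list length 1090 were gained and 899 lost, against 386 to 457. Strong gained peaks numbered 69 and strong lost peaks 2, against 0 to 2 in mixed splits. The strong gained peaks of highest −log10 q were at chromosome 19, 33153120 to 33153921 (fold 12.2 ± 0.758, SD, n = 2 pools), chromosome 18, 51621141 to 51622124 (11.0 ± 0.827), chromosome 14, 20954219 to 20954890 (12.4 ± 1.35) and chromosome 12, 14216531 to 14217162 (14.2 ± 1.78). The 2 strong lost peaks were at chromosome 11, 79097208 to 79097439 (3.43 ± 0.350 in vehicle) and chromosome 9, 106138414 to 106138842 (4.59 ± 1.09). Without TCPOBOP pool 1, TCPOBOP pool 2, vehicle pool 1 or vehicle pool 2 the regions called higher numbered 215, 226, 288 and 272 and those called lower 49, 27, 21 and 31; from these 4 libraries alone they numbered 993 and 464, and among regions called in all 16 pools 215 and 67. Leaving out any 1 pool raised the gained peaks to 2135 to 5250 and the lost to 1898 to 4686.

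The female 27 h pools were compared in the same way. Signal was higher after TCPOBOP at 946 of 25502 regions, with a median of log2 0.96 (1.95-fold), and lower at 752, with a median of −0.89. Chromosome 18, 68650572 to 68651869 had the largest rise, 7.95-fold from 1.02 to 8.13 in scaled pileup (log2 2.99 ± 0.21, SE, n = 2 pools per group, limma adjusted p = 1.36e-10). The chromosome 7 regions at 26681892 to 26682863 and 26672712 to 26673610 rose by log2 2.98 ± 0.23 (adjusted p = 3.89e-09) and 2.83 ± 0.18 (adjusted p = 2.21e-11). Chromosome 12, 63870068 to 63871129 was log2 2.65 ± 0.18 higher (adjusted p = 1.20e-10); scaled vehicle pileup there was 1.18 in these pools and 3.43 to 5.25 in the vehicle pools of the other 3 experiments. Chromosome 16, 31651669 to 31652628 changed by log2 −1.53 ± 0.18 (adjusted p = 1.00e-06), chromosome 2, 167828778 to 167829640 by −1.505 ± 0.18 (adjusted p = 2.60e-06), chromosome 2, 24042817 to 24044006 by −1.43 ± 0.19 (adjusted p = 1.51e-05) and chromosome 7, 56606881 to 56607881 by −1.34 ± 0.17 (adjusted p = 4.52e-06).

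Of 34386 peaks shared by the female 27 h TCPOBOP pools, 3342 were gained (9.72%, CI 9.41 to 10.04), and 673 of 28560 vehicle peaks were lost (2.36%, CI 2.18 to 2.54). Mixed splits gave 404 to 1446. At equal list length 1673 were gained and 1026 lost, against 440 to 630. Strong gained peaks numbered 226 and strong lost peaks 26, against 0 to 4 in mixed splits. The strong gained peaks of highest −log10 q were at chromosome 14, 20954199 to 20954893 (fold 11.4 ± 0.649, SD, n = 2 pools), chromosome 17, 79037702 to 79038834 (9.94 ± 0.101), chromosome 4, 25298813 to 25299539 (14.3 ± 0.979) and chromosome 12, 14216295 to 14217301 (10.7 ± 0.122). The strong lost peaks of highest −log10 q were at chromosome 2, 7181696 to 7182326 (7.86 ± 0.0623 in vehicle) and chromosome 4, 127199184 to 127199732 (8.61 ± 0.332). Without TCPOBOP pool 1, TCPOBOP pool 2 or vehicle pool 1 the regions called higher numbered 482, 427 and 563 and those called lower 331, 268 and 260. Leaving out any 1 pool raised the gained peaks to 4450 to 6913 and the lost to 1378 to 3812.

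**Figure D1:**
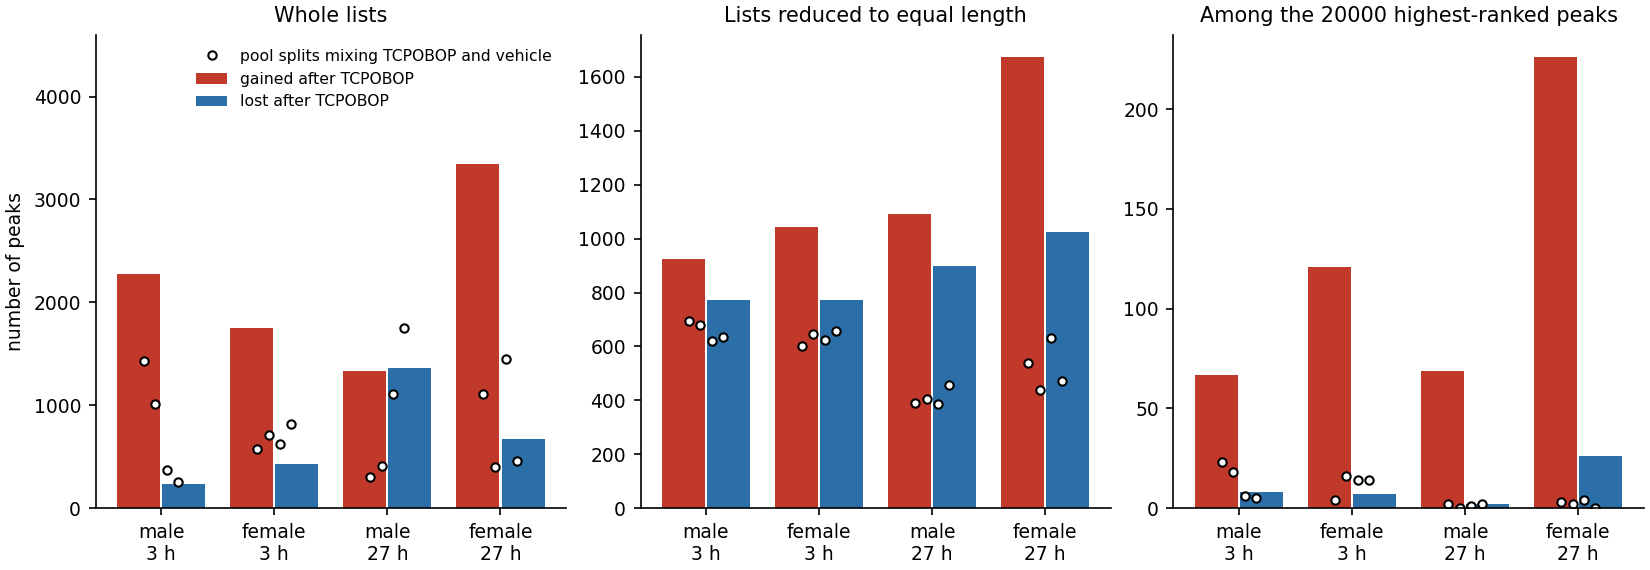
Number of peaks gained (red bars) and lost (blue bars) after TCPOBOP in each sex and time, in whole lists, in lists of equal length and among the 20000 highest-ranked peaks, with open circles for the 2 splits that mix TCPOBOP and vehicle pools, each counted in both directions. Among the highest-ranked peaks the gained counts of 67, 121, 69 and 226 lie above every circle.

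The centring of pileup affected both the balance and the number of the regions called. Higher regions were 85.0% of those called in males at 3 h, 93.0% in females at 3 h, 79.9% in males at 27 h and 55.7% in females at 27 h. Without centring, these shares were 99.0%, 95.1%, 93.3% and 72.2%, with 291, 154, 705 and 942 higher and 3, 8, 51 and 362 lower regions. The median change of all tested regions was then log2 0.15 in males at 3 h and 0.11 in males at 27 h, and with centring −0.03 and −0.01. Centring on the 5000 regions with the highest signal gave 76.5%, 94.8%, 76.9% and 66.5% in the same order.

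The regions at chromosome 7 between 26672712 and 26715240 stood out by their p-values and were followed in all 4 comparisons. Of its 13 regions, 6 had higher signal or a strong gained peak in at least 1 comparison. Regions with higher signal numbered 3 of 3 tested in each sex at 3 h and 4 of 4 in each sex at 27 h. The peak at 26676827 to 26677554 was gained in females at 3 h and in both sexes at 27 h, as was the one at 26713932 to 26715240. Between them, 26687223 to 26687691 was lost in both sexes at 27 h. At 26674300 to 26675132 the increase in males was log2 1.29 ± 0.20 at 3 h (adjusted p = 0.00130) and 0.83 ± 0.20 at 27 h (adjusted p = 0.0203), but the 3 h call was lost without TCPOBOP pool 1 (adjusted p = 0.0667). The 27 h call was lost without any 1 of the 4 pools (adjusted p = 0.146 and 0.186 without TCPOBOP pools 1 and 2, 0.327 and 0.0500027 without vehicle pools 1 and 2).

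**Figure D2:**
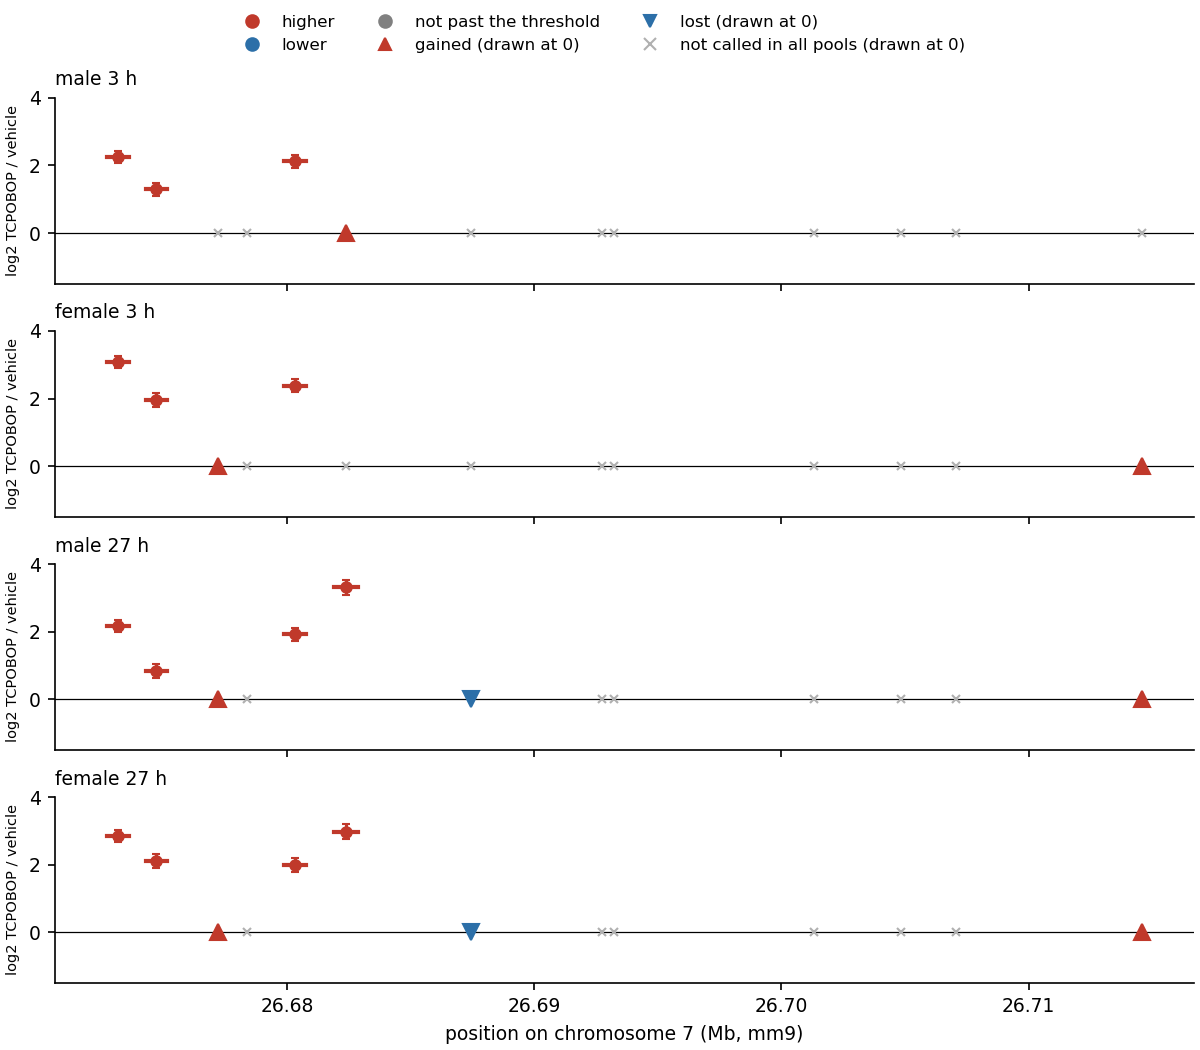
Log2 change of scaled pileup, TCPOBOP over vehicle, for regions on chromosome 7 between 26672712 and 26715240 in each sex and time, with error bars of 1 SE (n = 2 pools per group); triangles mark gained or lost peaks and crosses regions not called in all pools, drawn at 0. The region at 26672712 to 26673610 lies at 2.25, 3.08, 2.17 and 2.83 in the 4 comparisons.

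Males and females were compared to see whether TCPOBOP changed the same regions. At 3 h, 67 regions had higher signal in both sexes, of 139 called higher in males and 206 in females among 19981 regions tested in both, where independent lists would share 1.43. No region was called lower in both (0.0187 for independent lists; 22 in males and 17 in females) and 0 were called in opposite directions. At 27 h, 287 regions were higher in both sexes (13.98 for independent lists) and 59 were lower in both (3.02), with 0 called in opposite directions. These pileup calls and those compared below share an estimate of spread per region, which by itself can raise the overlap. The numbers for independent lists are therefore references and not tests. Among regions called in either sex, 84.9% had the same sign of change in both at 3 h and 92.6% at 27 h. Changes correlated across regions at r = 0.182 and rho = 0.0828 at 3 h and at r = 0.580 and rho = 0.454 at 27 h, regions not being independent replicates. The test of the difference between the sexes itself called 1 region at 3 h and 2 at 27 h.

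Regions gained in both sexes numbered 238 at 3 h and 352 at 27 h, where independent lists would share 145 and 119 of the regions free to change in both, and regions lost in both numbered 5 and 53 (3.03 and 20.7). Opposite changes were seen at 3 h in 27 regions gained in males and lost in females and in 8 with the reverse (35.1 and 12.5 for independent lists), and at 27 h in 6 and 32 (25.4 and 97.3). The odds ratio of concordance was 5.45 at 3 h (95% CI 1.31 to 20.5) and 94.9 at 27 h (CI 37.2 to 291). With lists of equal length it was 16.7 (CI 7.11 to 41.9) and 176 (CI 74.5 to 466), and 41 regions at 3 h and 87 at 27 h were lost in both sexes (25.6 and 39.2 for independent lists). The regions gained in both sexes at 3 h with the best lowest rank were chromosome 10, 80420505 to 80421154 (mean fold 7.65 ± 1.09, SD, n = 4 pools) and chromosome 4, 25298813 to 25299549 (12.9 ± 2.47). Those at 27 h were chromosome 14, 20954198 to 20955082 (11.9 ± 1.04), chromosome 12, 14216227 to 14217372 (12.5 ± 2.28) and chromosome 17, 79037702 to 79038835 (10.7 ± 0.970). Regions lost in both sexes at 27 h included chromosome 9, 106138375 to 106138863 (mean fold 4.23 ± 0.752 in vehicle, n = 4 pools) and chromosome 7, 26687223 to 26687691 (4.61 ± 0.567). Leaving out any 1 pool lowered the odds ratio to 2.04 to 3.51 at 3 h, where without female TCPOBOP pool 1 it was 2.04 with an interval that reaches below 1 (CI 0.830 to 4.72), and to 21.9 to 60.1 at 27 h.

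**Figure D3:**
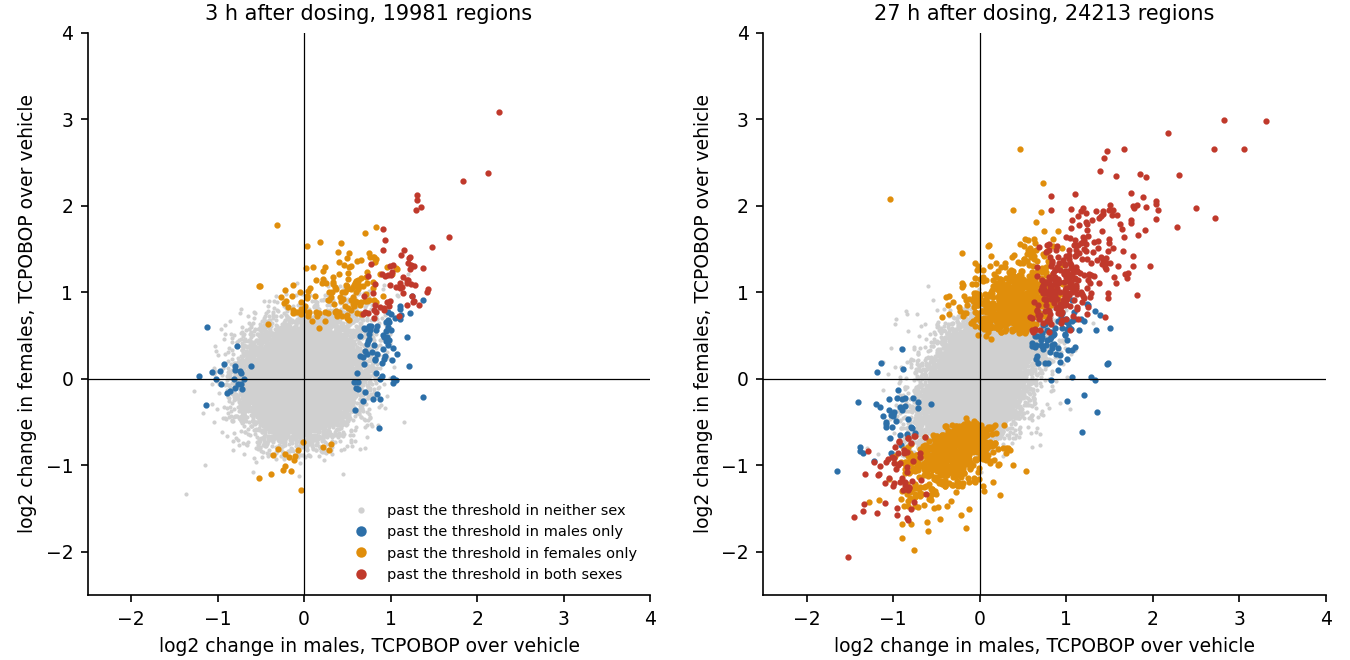
Log2 change after TCPOBOP in females against that in males for regions called in all pools of both sexes, at 3 h (19981 regions) and 27 h (24213 regions); colours show in which sex a region passed the threshold. Regions past the threshold in both sexes (67 higher at 3 h, 287 higher and 59 lower at 27 h) lie in the quadrants of equal sign.

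The 2 times were compared within each sex. In males, 80 regions were higher at both times (2.30 for independent lists) and 0 lower at both (0.125). In females, 137 were higher at both times (8.41) and 4 lower at both (0.503). In the pileup test no region was called in opposite directions in either sex. The test of the difference between times called 6 regions in males and 37 in females; in both sexes chromosome 16, 31651669 to 31652628 was among them, with log2 changes of 0.04 at 3 h and −1.35 at 27 h in males and −0.15 and −1.53 in females. Regions gained at both times numbered 114 in males (58.3 for independent lists) and 283 in females (146), and those lost at both 11 (5.84) and 13 (7.07). Opposite changes were seen in males in 51 regions gained at 3 h and lost at 27 h (57.7) and in 3 with the reverse (5.90). In females these were 19 (29.0) and 11 (35.5). The odds ratio of concordance was 8.09 in males (CI 2.02 to 47.1) and 17.3 in females (CI 6.23 to 49.2), and 2.73 to 8.25 and 3.74 to 8.54 when any 1 pool was left out. With lists of equal length it was 8.01 and 16.5.

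Across all 4 comparisons 37 regions were gained and 1 was lost. Those with the best lowest rank were chromosome 4, 19237874 to 19239234, with a mean fold of 11.3 ± 2.098 (SD, n = 8 TCPOBOP pools), chromosome 12, 14216227 to 14217372 (11.2 ± 2.13), chromosome 9, 116095802 to 116096872 (8.66 ± 0.940), chromosome 2, 130750540 to 130751141 (4.82 ± 0.959) and chromosome 16, 14059190 to 14059873 (8.53 ± 2.42). The region lost in all 4 was chromosome 9, 106138375 to 106138863, with a fold of 4.53 ± 0.665 in the 8 vehicle pools.

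Vehicle livers of both sexes were compared as a check on the labels and to describe sex differences without treatment. The 8 male lists held 62 to 85 peaks on chromosome Y and each of the 8 female lists held 1. In every vehicle list of males and no vehicle list of females, 575 regions were present (310 for independent lists), 42 of them on chromosome Y, and 38 were present in every vehicle list of females and none of males (9.82), 11 of them on chromosome X. The male-only regions outside chromosome Y with the best lowest rank were chromosome 8, 27704205 to 27704976 (mean fold 13.4 ± 1.19, SD, n = 4 pools), chromosome 1, 61696375 to 61697115 (12.2 ± 1.21), chromosome 7, 15031676 to 15032550 (10.2 ± 0.316) and chromosome 13, 20752689 to 20753565 (12.6 ± 2.39). Of the 10 female-only regions with the best lowest rank, 7 lay on chromosome X and 6 of these between 47925174 and 47976703. The first was chromosome X, 47964577 to 47965595 (13.3 ± 2.61), and the one outside that stretch was chromosome X, 72980025 to 72980299 (11.1 ± 3.33). Of these 7, 6 were present in all 8 female lists and absent from all 8 male lists.

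Regions called in all 4 vehicle pools of a time were tested for signal as well. Signal was higher in males at 496 regions and in females at 552 of 21051 at 3 h, and at 1814 and 2198 of 26167 at 27 h. Which sex had more depended on the scaling. Without centring the counts were 295 and 378 at 3 h and 2370 and 646 at 27 h, and centred on the 5000 regions with the highest signal 726 and 362, and 1921 and 1888. With loess scaling they were 567 and 513 at 3 h, and among regions called in all 16 pools 1667 and 1094 at 27 h. Regions higher in males at both times numbered 140 (37.6 for independent lists) and those higher in females at both 63 (31.9), but 63 were higher in opposite sexes at the 2 times, and the differences correlated at r = 0.0652 and rho = −0.0147 across 19330 regions. By presence of peaks the odds ratio of concordance was 162 (CI 26.8 to 6619), and of the regions female-only at 3 h, 134 were male-only at 27 h (223 for independent lists) and 38 female-only (9.82). The sexes were studied under different experiment codes, so these values hold any difference between experiments. Without female vehicle pool 1, female vehicle pool 2 or male vehicle pool 1 the regions higher in males at 3 h numbered 219, 142 and 158 and those higher in females 152, 80 and 271, and at 27 h without female vehicle pool 2, male vehicle pool 1 or male vehicle pool 2 they numbered 751, 735 and 856, and 700, 666 and 986. The odds ratio was 16.3 to 125 when any 1 pool was left out, and 46.0 with lists of equal length.

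The effect of TCPOBOP on sex-specific regions was measured with regions defined in the vehicle pools of the other time, so that no vehicle list was used for both steps. These classes held only in part at the other time: 849 of the 1294 regions female-only at 3 h were in the vehicle pools of males at 27 h, against 531 in those of females. The size of the classes depended on list length. At 27 h 4970 regions were male-only and 482 female-only in whole lists, and 1919 and 1160 at equal length. The male 3 h TCPOBOP lists, of 39192 and 32791 peaks, were also longer than the vehicle lists, of 31096 and 29216. The shares below are from whole lists and do not separate sex or TCPOBOP from list length. Gain was counted among regions absent from the vehicle pools of the comparison. In males at 3 h, 341 of 2415 male-only regions were gained (14.1%, CI 12.8 to 15.6), 9 of 443 female-only regions (2.03%, CI 0.933 to 3.82) and 682 of 2467 present in both sexes (27.6%, CI 25.9 to 29.5). In females at 3 h these were 224 of 3295 (6.80%, CI 5.96 to 7.71), 9 of 380 (2.37%, CI 1.09 to 4.45) and 475 of 2316 (20.5%, CI 18.9 to 22.2). In males at 27 h they were 16 of 76 (21.1%, CI 12.5 to 31.9), 28 of 218 (12.8%, CI 8.71 to 18.03) and 8 of 43 (18.6%, CI 8.39 to 33.4), and in females at 27 h 133 of 766 (17.4%, CI 14.7 to 20.2), 67 of 384 (17.4%, CI 13.8 to 21.6) and 183 of 465 (39.4%, CI 34.9 to 44.0). Loss was counted among regions present in the vehicle pools. In males at 3 h, 29 of 1216 male-only regions were lost (2.38%, CI 1.60 to 3.41), 0 of 4 female-only regions and 52 of 20665 of both sexes (0.252%, CI 0.188 to 0.330). In females at 3 h these were 56 of 717 (7.81%, CI 5.95 to 10.02), 1 of 49 (2.04%, CI 0.0517 to 10.9) and 125 of 21226 (0.589%, CI 0.490 to 0.701). In males at 27 h they were 25 of 1184 (2.11%, CI 1.37 to 3.10), 41 of 849 (4.83%, CI 3.49 to 6.49) and 27 of 20895 (0.129%, CI 0.0852 to 0.188), and in females at 27 h 16 of 374 (4.28%, CI 2.46 to 6.85), 28 of 531 (5.27%, CI 3.53 to 7.53) and 65 of 19354 (0.336%, CI 0.259 to 0.428).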

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

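The 4 tests of differing effects below were chosen after the lists were seen, as was the pileup test they belong to. All 4 come from the contrast of 2 TCPOBOP effects in limma, and each contrast also differs in experiment.

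Between the sexes at 3 h, the effect of TCPOBOP differed at 1 region, chromosome 17, 16997376 to 16998452, with a log2 change of 0.60 in females and −1.13 in males (difference 1.73 ± 0.27, SE, adjusted p = 0.0196). Between the sexes at 27 h it differed at 2 regions, both on chromosome 12. At 63870068 to 63871129 the log2 change was 2.65 in females and 0.47 in males (difference 2.18 ± 0.26, adjusted p = 5.39e-05), and at 64118600 to 64119481 it was 2.08 in females and −1.04 in males (difference 3.12 ± 0.48, adjusted p = 0.00522). At the first of these, pileup scaled to 1000000 tags was 7.40 after TCPOBOP in females and 7.25 in males, and after vehicle 1.18 and 5.25. Leaving out 1 pool gave 0 to 9 regions at 3 h and 1 to 6 at 27 h: 0 without female TCPOBOP pool 2, either female vehicle pool or male TCPOBOP pool 2, 3 without male TCPOBOP pool 1 and 9 without male vehicle pool 1 at 3 h, and 1 without female TCPOBOP pool 1 or male vehicle pool 1, 6 without female vehicle pool 1 and 4 without female vehicle pool 2 at 27 h. With no mean trend in the prior limma called 0 regions at 3 h and 1 at 27 h, and without centring 0 and 2. At an unadjusted p of 0.05 the limma contrasts held 2059 of 19981 regions at 3 h and 1252 of 24213 at 27 h. With no difference at any region a share of about 0.05 would pass, close to the share seen at 27 h. Such a share cannot show equal effects with 2 pools per group. At 27 h the 920 regions called higher in females had medians of log2 0.96 in females and 0.56 in males, and the 710 called lower −0.88 and −0.34. The 368 called higher in males had 1.03 in males and 1.08 in females, and the 103 called lower −0.94 and −0.85. Selection raises the change in the sex used for it, and these sets were not tested.

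Between 27 h and 3 h, the effect differed at 6 regions in males and at 37 in females. In males, chromosome 5, 129084925 to 129086402 changed by log2 3.19 at 27 h and 1.23 at 3 h (difference 1.95 ± 0.32, adjusted p = 0.0474), and the other 5 had adjusted p = 0.0497. They were chromosome 8, 124241810 to 124242819 (log2 1.86 at 27 h and 0.05 at 3 h), chromosome 6, 51341522 to 51342549 (1.29 and −0.22), chromosome 16, 31651669 to 31652628 (−1.35 and 0.04), chromosome 17, 31397993 to 31398788 (−0.72 and 0.70) and chromosome 1, 72772092 to 72773160 (−0.95 and 0.80). In females the difference of lowest p was again at chromosome 12, 63870068 to 63871129 (2.65 at 27 h and 0.48 at 3 h, adjusted p = 8.41e-05), followed by chromosome 13, 22010619 to 22011563 (2.40 and 0.10, adjusted p = 0.000556). The absolute change was larger at 27 h in 35 of the 37 regions in females and in 6 of 6 in males. The sign was opposite between times in 26 of 37 and 4 of 6. Selection on the difference of effects favours opposite signs, and in each sex 0 regions were called in opposite directions at both times. In males 0 regions were called by limma with loess scaling, without centring or with no mean trend in the prior, and in females 10 with no mean trend. Of 22332 regions tested in males and 20050 in females, 1680 and 2180 had an unadjusted limma p under 0.05. In males, leaving out 1 pool gave 0 regions without any of the 27 h pools or 3 h vehicle pool 2, 1 without either 3 h TCPOBOP pool, and 5 without 3 h vehicle pool 1, with 1680 regions at an unadjusted p of 0.05 in all pools. In females it gave 4 without 3 h vehicle pool 1, 9 and 10 without 27 h TCPOBOP pools 1 and 2, 11 without 3 h vehicle pool 2, 21 and 93 without 3 h TCPOBOP pools 1 and 2, and 42 and 29 without 27 h vehicle pools 1 and 2.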

How the results depend on the processing

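The pileup test and its settings other than the replicate block and the left-out pools were chosen after the data were seen, as were anchoring on pool 2, merged regions, and the 20000 highest or equal lengths for concordance. Among 65 changes of named regions, 815 of 896 values under alternatives kept their direction and side of the threshold, 81 kept direction only and 0 reversed. Of 428 alternative values of 32 counts, 207 stayed within 1.5 times of the reported count and 221 moved. Of 65 values of 5 odds ratios, 55 stayed within the reported interval and 10 moved, all of these with a pool left out. Gained peaks exceeded lost peaks under all 12 settings in 3 comparisons and under 3 of 12 in males at 27 h, strong gained exceeded strong lost under all 12 in all 4, and higher regions exceeded lower ones under all 14 in all 4. With the 20000 highest, 4 odds ratios could not be computed, since no region was lost in both comparisons or changed in opposite directions, and that of vehicle livers was infinite (lower limit 82.7). Counts between lists of unequal length also hold the difference in length, and 2 pools per group limit the pileup test. With 1 pool left out, the lone pool is assumed to vary like the other groups. The 40000 highest hold whole lists except in 5. The planned gene lists, motif search and named genes were not run. The cause of the movements below was not tested.

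With −log10 q of at least 10, gained peaks numbered 129 (male 3 h), 147 (female 3 h), 200 (male 27 h) and 490 (female 27 h). Lost peaks numbered 2 (male 3 h), 2 (female 3 h), 75 (male 27 h) and 33 (female 27 h). With equal list lengths, gained peaks numbered 924 (male 3 h), 1044 (female 3 h) and 1673 (female 27 h). Lost peaks numbered 774 (male 3 h), 771 (female 3 h), 899 (male 27 h) and 1026 (female 27 h). With reciprocal overlap of 50%, lost peaks numbered 678 (male 3 h), 917 (female 3 h) and 1500 (female 27 h). Strong gained peaks numbered 234 (male 3 h), 249 (female 3 h), 162 (male 27 h) and 610 (female 27 h). Strong lost peaks numbered 107 (male 3 h), 128 (female 3 h), 56 (male 27 h) and 234 (female 27 h). With summits within 250 bp, lost peaks numbered 540 (male 3 h), 704 (female 3 h) and 1366 (female 27 h). Strong gained peaks numbered 194 (male 3 h), 224 (female 3 h), 226 (male 27 h) and 502 (female 27 h). Strong lost peaks numbered 177 (male 3 h), 157 (female 3 h), 1.4e2 (male 27 h, rounded) and 362 (female 27 h). With the 10000 highest, strong gained peaks numbered 4 (male 3 h), 9 (female 3 h), 10 (male 27 h) and 31 (female 27 h). Strong lost peaks numbered 1 (male 3 h), 0 (female 3 h), 0 (male 27 h) and 0 (female 27 h). With the 40000 highest, strong gained peaks numbered 2280 (male 3 h), 1752 (female 3 h), 1008 (male 27 h) and 3289 (female 27 h). Strong lost peaks numbered 235 (male 3 h), 427 (female 3 h), 812 (male 27 h) and 673 (female 27 h). Ranked by fold enrichment, strong gained peaks numbered 163 (male 3 h), 106 (male 27 h) and 371 (female 27 h). Strong lost peaks numbered 27 (male 3 h), 18 (female 3 h), 11 (male 27 h) and 54 (female 27 h).

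With 4 libraries only, regions higher after TCPOBOP numbered 14 (male 3 h), 149 (female 3 h) and 993 (male 27 h). Regions lower numbered 0 (male 3 h), 10 (female 3 h) and 464 (male 27 h). Male-biased vehicle regions numbered 323 (3 h). With no mean trend in the prior, regions higher after TCPOBOP numbered 50 (male 3 h) and 146 (female 3 h). Regions lower numbered 6 (male 3 h) and 10 (female 3 h). Female-biased vehicle regions numbered 328 (3 h). Regions whose change differed numbered 0 (between sexes at 3 h), 1 (between sexes at 27 h), 0 (between times in males) and 10 (between times in females). Scaled to tags but not centred, regions higher after TCPOBOP numbered 291 (male 3 h) and 154 (female 3 h). Regions lower numbered 3 (male 3 h), 8 (female 3 h), 51 (male 27 h) and 362 (female 27 h). Male-biased vehicle regions numbered 295 (3 h). Female-biased vehicle regions numbered 646 (27 h). Regions whose change differed numbered 0 (between sexes at 3 h) and 0 (between times in males). With regions called in all 16 pools, regions higher after TCPOBOP numbered 215 (male 27 h). Regions lower numbered 67 (male 27 h). Female-biased vehicle regions numbered 1094 (27 h). Centred on the 5000 highest regions, female-biased vehicle regions numbered 362 (3 h). With loess scaling, regions whose change differed numbered 0 (between times in males).

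With the replicate number as a block, regions lower numbered 16 (male 3 h). Male-biased vehicle regions numbered 235 (3 h) and 791 (27 h). Female-biased vehicle regions numbered 154 (3 h) and 798 (27 h). The block was fitted within each experiment, so these vehicle contrasts compare values fitted for pool 1 and not group means. They are less precise and are not the sex difference adjusted for replicate number. Regions whose change differed numbered 0 (between times in males). Equal pool numbers gave no sign of pairing: deviations from group means of equally numbered pools correlated across regions at −0.0259 (male 3 h), 0.0227 (female 3 h), 0.0568 (male 27 h) and −0.0266 (female 27 h). The remaining counts of calls moved by less than 1.5 times with the block.

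Leaving out 1 pool at a time gave gained peaks of 3927 to 7828 (male 3 h), 2988 to 4315 (female 3 h), 2135 to 5250 (male 27 h) and 4450 to 6913 (female 27 h). Lost peaks were 420 to 1519 (male 3 h), 1239 to 1787 (female 3 h), 1898 to 4686 (male 27 h) and 1378 to 3812 (female 27 h), strong gained peaks 212 to 355 (male 3 h), 223 to 347 (female 3 h), 87 to 114 (male 27 h) and 287 to 522 (female 27 h), and strong lost peaks 24 to 105 (male 3 h), 77 to 103 (female 3 h), 5 to 34 (male 27 h) and 71 to 116 (female 27 h). Regions higher after TCPOBOP were 14 to 146 (male 3 h), 91 to 155 (female 3 h), 215 to 288 (male 27 h) and 427 to 793 (female 27 h), and lower 2 to 14 (male 3 h), 1 to 67 (female 3 h), 21 to 49 (male 27 h) and 260 to 673 (female 27 h). Vehicle regions higher in males were 142 to 434 (3 h) and 735 to 1610 (27 h), and in females 80 to 448 (3 h) and 666 to 1658 (27 h). Regions whose change differed were 0 to 9 (between sexes at 3 h), 1 to 6 (between sexes at 27 h), 0 to 5 (between times in males) and 4 to 93 (between times in females). Odds ratios were 2.04 to 3.51 (sexes, 3 h), 21.9 to 60.1 (sexes, 27 h), 2.73 to 8.25 (times, males), 3.74 to 8.54 (times, females) and 16.3 to 125 (vehicle, sexes).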

Other observations

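Of the tests in this part, those on gained and lost peaks, on sex-specific regions of vehicle livers and on neighbouring regions were chosen only after the result was seen; those on sex-biased regions and on the time course were set before, but the rule for which comparisons of sex-biased regions can be read was added after their values were seen.

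Regions with higher signal after TCPOBOP often lay near each other. The largest groups of such regions and strong gained peaks, each at most 100 kb apart, were on chromosome 13, 21946817 to 22143338 (11 regions) and on chromosome 7, 105495896 to 105572430 (11 regions). The chromosome 13 group was higher at 10 of 14 tested regions in females at 27 h and 6 of 14 in males at 27 h, with medians of log2 1.09 and 0.54, but at 1 of 14 in females and 0 of 16 in males at 3 h, with medians of 0.00 and 0.12. A second group on chromosome 13, 23492618 to 23611611, was higher at 7 of 10 regions in females and 1 of 12 in males at 27 h and at 0 of 15 in both sexes at 3 h. The chromosome 7 group at 105495896 to 105572430 was higher at 8 of 9 regions in females and 5 of 9 in males at 27 h, and at 3 of 8 and 1 of 8 at 3 h.

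On chromosome 19, 39286313 to 39408416, most of the response was in gained peaks. Of 26 regions there, 12 were gained in females and 8 in males at 27 h, and 4 and 3 at 3 h, while 39363512 to 39363916 was lost in females at both times and in males at 27 h. All 4 regions tested in males at 27 h were higher, by up to log2 2.11. On chromosome 6, 66931377 to 67120935, 6 of 11 regions in females and 4 of 13 in males were higher at 27 h, and 1 of 10 and 4 of 9 at 3 h.

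Such neighbourhoods are a hypothesis of locus-wide opening, tested against the uneven spacing of hypersensitive regions. Higher regions with another higher region within 100 kb numbered 27 in males at 3 h, 57 in females at 3 h, 217 in males at 27 h and 448 in females at 27 h. The highest of 1000 random draws of tested regions matched on signal were 15, 32, 96 and 242. In each comparison p was 0.001, the smallest such draws can give (random draws of regions, one-sided). This p takes regions as independent units and does not measure the spread between pools. The lowest ratio of observed to highest drawn was 1.78. Lower regions were also near each other at 27 h, 23 of 140 in males (highest draw 17) and 324 of 752 in females (highest draw 159), and at 3 h 0 of 26 in males and 0 of 18 in females were. Neighbouring regions may therefore respond together, although the draws do not separate shared control from copy-number or mapping differences between pools.

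Gained peaks outnumbered lost peaks 9.70 to 1 in males at 3 h, 4.10 in females at 3 h and 4.97 in females at 27 h, but 0.977 to 1 in males at 27 h, where the vehicle pools held more tags in sum. A candidate explanation for this spread is unequal depth and list length. With all lists reduced to equal length the ratios were 1.19, 1.35, 1.63 and 1.21, and the highest was 1.37 times the lowest. Equal lengths bring gained and lost counts together whatever the cause, so this value decides nothing. Unequal list length and a difference in the response to TCPOBOP cannot be told apart for this spread. Each ratio also moved with the setting, left-out pools included. Over 12 settings it ran from 1.19 to 64.5 in males and 1.35 to 73.5 in females at 3 h. At 27 h it ran from 0.491 to 2.77 in males and 1.17 to 14.8 in females.

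Strong gained peaks outnumbered strong lost peaks in all 4 comparisons and in all 12 alternative settings. These varied overlap, ranking, chromosomes kept, the anchoring pool and the pools left out. The lowest ratio over them was 1.10 in males and 1.43 in females at 3 h, and 1.24 in males and 1.39 in females at 27 h. Depth alone argues for the reverse in males at 27 h, where vehicle pools held more tags in sum, yet 69 strong gained peaks were 34.5 times the 2 strong lost. Among settings with any lost peak that is the highest ratio, and with the 10000 highest it was 10 against 0; the lowest, with the 40000 highest, was 1.24 (1008 against 812). Variation between pools would give mixed splits as large as the real ones, but strong gained peaks were at least 2.91 times the highest count of the 2 mixed splits. The ratio of 34.5 goes against depth in tags as the whole cause in males at 27 h only. At 3 h both TCPOBOP pools held more tags than either vehicle pool in each sex. Female pools at 27 h held 25065722 and 30340709 tags after TCPOBOP and 28624325 and 18044366 after vehicle. Mixed splits put 1 pool of each treatment on both sides, so they cannot decide depth in these comparisons. The value of 2.91 goes against pool variation as the whole cause. Depth outside males at 27 h, a difference in enrichment between libraries and a net opening of chromatin stay open.

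Among regions female-only in the 3 h vehicle lists, 134 were male-only and 38 female-only at 27 h, a ratio of 3.53. Unequal depth of male and female pools could give this, since the 27 h male vehicle lists held 42622 and 44404 peaks and the female ones 37824 and 32596. At equal list length the ratio was 0.567, with 51 male-only and 90 female-only regions, as that explanation needs. Equal length did not fix this outcome, since 1919 regions were male-only and 1160 female-only at 27 h in those lists. Independent lists would share 223 and 9.82 regions in the whole lists and 111 and 45.6 at equal length, so an excess of male-only regions needs no link between the times. A difference between the experiments stays open.

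The hypothesis that TCPOBOP moves sex-biased regions toward the other sex was left open only by a rule set after the values were seen. With sex bias taken from the vehicle pools of the other time, the median log2 change of male-biased minus female-biased regions was 0.12 in males at 3 h, −0.01 in males at 27 h, −0.06 in females at 3 h and 0.14 in females at 27 h, so it moved as predicted in 1 of 4 comparisons. The bound set before the values were seen, at least 2 of 4 comparisons near 0 or of the other sign, was met and on its own rules the hypothesis out. For 3 h that bound took the bias to be present in the tested livers. Regions biased at 27 h had at 3 h a median log2 difference, male minus female vehicle, of −0.05 for the 1756 male-biased. It was −0.04 for the 1194 female-biased, so as a set neither class kept its bias at 3 h, although some regions did. Regions biased at 3 h had at 27 h 0.35 for the 414 male-biased and −0.00 for the 517 female-biased. The median over all vehicle regions tested at 27 h was −0.09, so only the male-biased set carried a bias that could move. In females at 27 h the median change was 0.08 for male-biased regions, −0.05 for female-biased and −0.05 for those without a called bias. In males at 27 h these were −0.005, 0.01 and −0.02. The 0.14 in females is the predicted change and the −0.01 in males is not, but no test compared the sexes. Of the regions called at both times 140 were higher in males at both, 63 in females at both and 63 in opposite sexes. Counting only comparisons whose bias carried over by more than log2 0.1 was decided after these values were seen; it replaced an earlier rule, also set afterwards, on the correlation over all 19330 regions (rho = −0.0147), which would set aside all 4.

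The hypothesis that changes at 3 h are larger by 27 h was tested on regions called higher at 3 h in 1 sex and measured in the other. For the 130 regions selected in males, the median log2 change in females was 0.74 at 3 h and 0.67 at 27 h, with a median difference of 0.00463. For the 204 selected in females, it was 0.61 and 0.77 in males, with a median difference of 0.27. Only the second passed the bound of 0.2, so the growth was not seen in both sexes.

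The 1 peak on chromosome Y in each female list was not scattered. In the 4 female 3 h lists it lay at 2769365 to 2769613, with fold enrichments of 27.4 to 32.5, and the same ends occurred in all 8 male lists, at folds of 6.16 to 27.2. In the 4 female 27 h lists it lay at 2776776 to 2777024, with folds of 27.7 to 34.6, and the same ends occurred in the 4 male 27 h lists, at 4.86 to 5.78. Both peaks were 249 bp wide.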
